A study of Homo sapiens with 243 samples.

How the data were processed

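Bulk RNA-seq values of sorted fractions of freshly resected human tumours were used, 243 libraries of 111 donors: 85 T cell, 105 myeloid (103 donors) and 53 live libraries, with a separate file of values per fraction. Per the labels' protocols, mRNA was isolated with a bead kit and amplified, and libraries were made with Nextera XT. Per the submitters' processing notes, reads were first aligned with BWA-mem to ribosomal RNA, including the mitochondrial, and then with STAR to GRCh38. Whether the aligned ribosomal reads were removed, the versions, the quantifier and the gene annotation are not given in the sources used here, and no strand-marking step is named. The deposited tables hold TPM, as made by the authors, and each library summed to between 999998.9 and 1000001.1. The tables also held 389 columns of other series, and no step used them. Depth is unknown, since TPM keeps none, so the precision of a low value cannot be given.

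Each table had 57992 rows. Rows without a symbol (14379, a median of 1.85% of TPM, from 0.54% to 5.02%) were left out, and rows of the 82 symbols found more than once were summed, which left 42573 symbols. Of these, 437 symbols, namely those placed on chromosome Y alone, XIST and TSIX, were left out of every test and table, and other genes of chromosome X were kept. As a check for mixed-up samples, sex-linked genes were compared between the fractions of 44 donors, and 0 disagreed. Gene positions are from the RefSeq annotation of GRCh38.p14. No pair of libraries was identical.

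Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(TPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes at 1 TPM or more in at least 25% of the libraries fitted were kept. Fractions were compared in 1 fit with tumour code as a covariate, specimens of the same donor and fraction being averaged. Tumour codes with at least 6 donors in a fraction were compared, by a moderated F test and then each code against the equally weighted mean of the others. Slopes on MRC1, or on the CD206 macrophage score, were fitted with tumour code as a covariate. The CD206 macrophage score was first standardised over the donors fitted, so its slopes are per SD of the score. For gene direction between codes, donors of a code were counted above or below the median of the other codes.

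The 36 gene lists were fixed before the data were examined: pan T cell, pan myeloid, leukocyte, CD206 macrophage, stress-responsive macrophage, classical monocyte, CXCR3 ligands, interferon response, cDC1, cDC2, mature dendritic cell, plasmacytoid dendritic cell, neutrophil, mast cell, CD8 T cell, cytotoxicity, NK cell, exhaustion, naive and memory T cell, regulatory T cell, tissue residence, T cell chemokine axis, B cell, plasma cell, epithelial, fibroblast, endothelial, intestinal, squamous, Mullerian, kidney and lung epithelium, alveolar macrophage, immediate early and heat shock, proliferation, and class II antigen presentation. A list score is the mean over its genes of log2(TPM + 1) standardised per gene within the fraction. Counts of list genes were made with adjustment over all genes and over the list alone. They are out of the list genes that passed the filter in that fit. The total of a list can thus be below its size and differ between comparisons. Scores were compared between codes by an F statistic and related to each other by Pearson's r and Spearman's rho, each with a two-sided permutation test of 100000 resamples, whose smallest possible p is 1e-05. The 17 relations and the 8 differences of relations were each adjusted as a family by Benjamini-Hochberg. The p-values of relations within library types were not adjusted.

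The genes named were set by a rule fixed before the data were examined. It took, among genes past the threshold with a mean log2 of at least 1, the 10 of largest change in each direction for T cell against myeloid, 5 for the other fraction contrasts and 3 for each code (higher only in live libraries), and the 10 of smallest p in each direction for the MRC1 slope. Members of the lists were named where they bear on a comparison. MRC1, CXCL9, CXCL10, SPP1, CD8A, CXCR3, XCL1, FLT3LG, XCR1 and CLEC9A were to be named whatever they showed. All 10 are given for the fraction contrasts, and only some of them for the codes and slopes. Segments of immunoglobulin and T cell receptor variable genes, mitochondrial and ribosomal protein genes, pseudogenes and clone names were passed over.

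Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, quantile normalisation, genes detected as a covariate, scores of other cell types as covariates, robust eBayes, the first specimen only, and donor as a block. For relations they were also the unstandardised mean, partial correlations given genes detected or other cells with the tumour code, pairs of the same specimen only, MRC1 alone and SPP1 alone. Another 4 were chosen after seeing the data: rescaling without the 13 mitochondrial genes, leaving out 24 libraries of low quality (under 10000 genes detected or over 50% mitochondrial), library type as a covariate, and leaving out the 17 mixed libraries. The scores of other cells were pan T cell, epithelial, fibroblast and B cell for myeloid libraries. They were pan myeloid, epithelial, fibroblast and B cell for T cell libraries, and leukocyte and epithelial for live libraries. Fits within library types used codes with at least 3 donors, a minimum also chosen after seeing the data. Relations were compared with random lists (10000 lists, each gene drawn from the 100 nearest in mean). Those comparisons were chosen after seeing the data, except for the CD206 macrophage and CXCR3 ligand relation and the interferon response.

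The pairing of fractions comes from the donor numbers of the labels. It was checked by the correlation of deviations from group means: the median within donors was 0.268 for T cell and myeloid (75 pairs, 68 over 0.1), 0.304 for T cell and live (46 pairs) and 0.28 for myeloid and live libraries (47 pairs), against -0.016 between donors of the same code.

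The fits were tested on simulated data. Of 200 genes changed, those changed by log2 1 were called in 97% of cases for T cell against myeloid, 19.4% for LUNG and 46.3% for KID myeloid, 40.3% for KID T cell and 29.9% for HNSC live libraries. At log2 2 these were 100%, 86.4%, 100%, 98.5% and 84.8%. Among unchanged genes 7 of 15754 were called for T cell against myeloid, 31 of 17176 for HNSC live libraries and 72 of 15000 for the MRC1 slope. A simulated r of 0.4 at n = 77 passed in 94.7% of 300 data sets and an r of 0 in 3%. Splits of the samples were drawn 100 times, the real one included. Random removals of myeloid libraries not of low quality, as many per code as were of low quality, were drawn 100 times for the MRC1 slope, a test chosen after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and, for reading files in R, data.table (version 1.17.8).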

Results

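RNA was measured in 243 libraries made from cell fractions sorted from freshly resected primary human tumours. The T cell fraction was sorted, per the labels, as conventional CD4+ and CD8+ T cells, with a separate gate for regulatory T cells, and gave 85 libraries from 85 donors. The myeloid fraction held HLA-DR+ cells that carried no lymphocyte marker and gave 1 library per donor apart from 2 donors with 2. The live fraction held all viable cells and gave 53 libraries from 53 donors. The tumours carried the codes CRC, GYN, HNSC, KID and LUNG. Among T cell donors 14 were CRC, 36 GYN, 12 HNSC, 19 KID and 4 LUNG. Among myeloid donors 13 were CRC, 37 GYN, 16 HNSC, 27 KID and 10 LUNG. Among live donors 9 were CRC, 29 GYN, 9 HNSC, 5 KID and 1 LUNG. In all, 51 donors gave the 3 fractions.

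The values were TPM (transcript abundance scaled to a fixed total per library), which keep no sequencing depth, so the depth per library is unknown. The number of genes at 1 TPM or more ranged from 7539 to 18464, with medians of 13406 in T cell, 13209 in myeloid and 14774 in live libraries. The 13 mitochondrial protein-coding genes held a median of 25.06% of TPM in T cell, 27.31% in myeloid and 29.44% in live libraries, with a range from 7.28% to 73.35%. The libraries fell into 2 types by the small RNA gene MIR12136 (chromosome 1, 632615 to 632685, GRCh38), which adjoins the mitochondrial pseudogene MTCO1P12. It was listed at 0 in the libraries of type A (39 T cell, 41 myeloid and 34 live). In those of type B (46, 64 and 19) it stood at 97.7 to 21901.4 TPM. The mean log2(TPM + 1) of mitochondrial tRNA genes differed as well, with a median of 0.0 in type A and 7.03 in type B. What sets the types apart was not tested, so MIR12136 serves only as a label of the type. The types were spread unevenly over the codes: all 10 LUNG myeloid libraries were type B, and 23 of the 37 GYN myeloid libraries were type A.

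The sorted fractions differed in the genes that define T cells and myeloid cells, which addresses what each gate contained. CD3E, a subunit of the T cell receptor complex, had a mean log2(TPM + 1) of 8.30 ± 1.31 (SD, n = 85 donors) in T cell, 5.63 ± 1.79 (n = 53) in live and 2.52 ± 2.15 in myeloid libraries (all donors with one). CD3E was 5.75 ± 0.26 (SE) higher on this scale in T cell than in myeloid libraries, a 53.9-fold difference (limma with Benjamini-Hochberg adjustment, adjusted p = 1.7e-56), with the direction in 76 of 77 donors who gave both. Other genes of large rise were CD3D (5.71 ± 0.27), the granzyme genes GZMK (5.60 ± 0.28) and GZMA (5.36 ± 0.30), the co-receptor gene CD8A (5.40 ± 0.27), CD96 (5.32 ± 0.29), CD3G (5.26 ± 0.24), the adhesion receptor gene CD2 (5.21 ± 0.26) and the costimulatory receptor gene ICOS (5.13 ± 0.26). Each was higher in at least 73 of the 77 donors. In the other direction stood IL1B, an inflammatory cytokine gene, at -4.69 ± 0.39 (lower in T cell libraries of 74 of 77 donors), with the Fc receptor chain gene FCER1G (-4.57 ± 0.30), lysozyme LYZ (-4.45 ± 0.29), the adaptor gene TYROBP (-4.34 ± 0.30), MPEG1 (-4.31), the transcription factor gene SPI1 (-4.26 ± 0.26), FCGR2A (-4.24), FCN1 (-4.23 ± 0.31) and OLR1 (-4.20). The antisense gene SLC39A13-AS1 (chromosome 11, 47381615 to 47409282) was at -4.31 ± 0.27, and because it overlaps SLC39A13 and no strand-marking step is named, its reads are uncertain in origin.

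**Figure D1:**
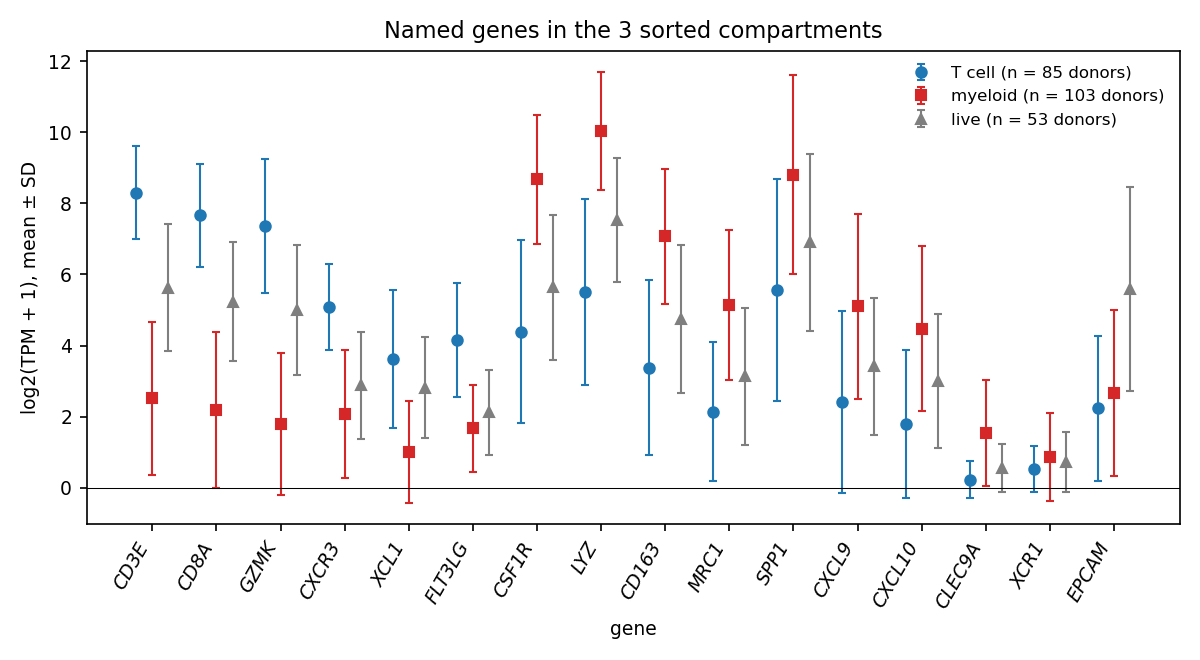
Mean log2(TPM + 1) of 16 genes in the T cell (n = 85 donors), myeloid (all donors) and live (n = 53) libraries, with error bars of 1 SD over donors. CD3E stood at 8.30 in T cell and 2.52 in myeloid libraries, while MRC1 stood at 5.14 in myeloid and 2.14 in T cell libraries.

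MRC1 (chromosome 10, 17809348 to 17911164), the gene of the macrophage mannose receptor CD206, was lower in T cell than in myeloid libraries by log2 -2.90 ± 0.28, in 69 of 77 donors. The chemokine genes CXCL9 (chromosome 4, 76001275 to 76007509; -2.60 ± 0.35) and CXCL10 (-2.68 ± 0.31), whose products bind CXCR3, and the secreted phosphoprotein gene SPP1 (-3.22 ± 0.40) were lower as well. CXCR3 itself was 3.03 ± 0.23 higher in T cell libraries, in 71 of 77 donors. The chemokine gene XCL1 (2.57 ± 0.23) and the cytokine gene FLT3LG (2.53 ± 0.20), whose products attract and sustain dendritic cells, were higher too. The dendritic cell gene CLEC9A was lower (-1.27 ± 0.15, in 55 of 77 donors). XCR1, the receptor for XCL1, was near the floor, with a mean of 0.87 in myeloid and 0.53 in T cell libraries. Its difference of -0.32 ± 0.14 (limma, adjusted p = 0.0351, lower in 40 of 77 donors) did not pass with a pseudocount of 0.1 or without the filter on low values.

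By the lists of T lymphocyte genes, 6 of 6 pan T cell, 2 of 2 CD8 T cell, 8 of 8 cytotoxicity (GZMH 4.71 ± 0.27, PRF1 4.09 ± 0.23) and 5 of 5 tissue residence genes (CXCR6 4.44 ± 0.24, ZNF683 3.52 ± 0.27) rose from myeloid to T cell libraries. All 7 NK cell list genes rose, from NCAM1 (0.59 ± 0.21) to KLRD1 (3.31 ± 0.25). All 5 regulatory T cell genes rose, among them FOXP3 (3.23 ± 0.23), the lineage factor of those cells. Its mean log2(TPM + 1) was 4.32 in T cell libraries, so RNA of regulatory T cell genes was present in a fraction gated as conventional. Of 7 naive and memory genes 6 rose, as LEF1 (4.63 ± 0.22) and IL7R (3.80 ± 0.26), and KLF2 did not pass (0.34 ± 0.21). Of 9 exhaustion genes 7 rose (TIGIT 3.85 ± 0.22, CTLA4 3.85 ± 0.30, TOX 3.22 ± 0.19), and HAVCR2 (-0.61 ± 0.23) and ENTPD1 (-0.56 ± 0.22), which macrophages also express, fell. Of the 7 T cell chemokine axis genes 5 rose (CCL5 4.62 ± 0.27), CCL3 fell (-2.04 ± 0.31) and CCL4 did not pass (0.48 ± 0.29). The leukocyte list, common to the fractions, had 3 of 6 higher, including PTPRC (1.34 ± 0.19), and LAPTM5 lower (-0.78 ± 0.17).

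By the lists of myeloid genes, 10 of 10 pan myeloid, 3 of 3 CXCR3 ligand, 4 of 4 cDC2, 2 of 2 plasmacytoid dendritic cell, 5 of 5 neutrophil, 4 of 4 alveolar macrophage and 7 of 7 class II antigen presentation genes were lower in T cell libraries. Examples are FCER1A (-3.39 ± 0.30), the granulocyte receptor gene CSF3R (-3.79 ± 0.29), MCEMP1 (-3.49 ± 0.32) and HLA-DRA (-3.29 ± 0.25). Counts here and below are out of the list genes that passed the filter. Here these were 2 of the 5 plasmacytoid dendritic cell and 4 of the 6 alveolar macrophage genes. Of the 18 CD206 macrophage genes 17 fell, as the complement gene C1QB (-3.77 ± 0.36), MS4A7 (-3.75 ± 0.28) and CD163 (-3.63 ± 0.31), and the transcription factor gene MAF, also active in T cells, rose (2.14 ± 0.18). Of 15 stress-responsive macrophage genes 7 fell (VEGFA -3.29 ± 0.25, HMOX1 -3.08 ± 0.25), the glucose transporter gene SLC2A1 rose (0.99 ± 0.20) and 7 did not pass. Of 8 classical monocyte genes 7 fell (CD300E -4.15 ± 0.29). Of 6 cDC1 genes 4 fell (WDFY4 -2.50 ± 0.17, BATF3 -1.49 ± 0.19) and CLNK rose (0.73 ± 0.19). Of 5 mature dendritic cell genes 4 fell (CCL22 -2.35 ± 0.32), and CCR7, shared with naive T cells, rose (1.98 ± 0.28). The interferon response list split, with 5 of 13 higher (GBP5 1.59 ± 0.21), 4 lower (IDO1 -2.44 ± 0.30) and 4 not passing.

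Among lists of other cell types, 0 of 5 mast cell and 0 of 6 fibroblast genes passed by limma between T cell and myeloid libraries, and TPSAB1, a mast cell tryptase gene, differed by 0.27 ± 0.42. Of 4 B cell genes CD79B rose (0.38 ± 0.15) and BANK1 fell (-1.73 ± 0.19). Of 3 plasma cell genes MZB1 rose (0.94 ± 0.27). With donor as a block, which pairs the libraries, 2 plasma cell genes also fell. Of 6 epithelial genes KRT19 fell (-0.71 ± 0.31). All 3 endothelial genes tested fell, as PECAM1 (-1.06 ± 0.21), which monocytes also express. Of tissue-specific lists, 1 of 3 intestinal (GPA33 0.33 ± 0.15) and 1 of 4 squamous genes rose (TP63 0.76 ± 0.22), 1 of 4 squamous (KRT5 -0.82 ± 0.31) and 1 of 3 kidney genes fell (ANGPTL4 -0.95 ± 0.22), and none of 4 Mullerian genes or of the 1 lung gene tested passed. Of 9 immediate early and heat shock genes 2 rose (DNAJB1 0.62 ± 0.23) and 5 fell (EGR1 -1.41 ± 0.21). Of 7 proliferation genes 4 rose (MKI67 0.70 ± 0.19), and only 2 with quantile normalisation or with the donor block. When adjusted over the list alone the counts were the same except that KRT19 and GPA33 did not pass.

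The test of T cell against myeloid libraries called 9858 of 15954 genes, 6604 higher and 3254 lower (67% higher). The median of all genes was 0.20 above 0, and with quantile normalisation it was 0.063 and 56.6% of calls were higher. With donor as a block the count was 10223. It was 8544 within type A and 7367 within type B libraries. Fold changes on the log2(TPM + 1) scale understate differences of genes near 0 TPM. In 14 of 85 T cell libraries the mean of the pan myeloid list exceeded that of the pan T cell list, and the reverse held in 3 myeloid libraries.

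Set against all viable cells, T cell libraries were higher in CD3E by 2.66 ± 0.31 (6.32-fold, limma adjusted p = 1.55e-13, in 50 of 51 donors), in the receptor genes CD5 (2.66 ± 0.29) and CD6 (2.64 ± 0.26), in CD3G (2.61 ± 0.29, in 51 of 51 donors) and in the chemokine gene CCL5 (2.57 ± 0.33). They were lower in the immunoglobulin genes IGHA1 (-3.86 ± 0.61) and IGHG2 (-3.37 ± 0.60), in the protease inhibitor gene PI3 (-3.62 ± 0.40, in 49 of 51 donors), in the neutrophil-attracting chemokine gene CXCL8 (-3.58 ± 0.44) and in S100A8 (-3.51 ± 0.40). CD8A (2.50 ± 0.32), CXCR3 (2.22 ± 0.27), FLT3LG (1.91 ± 0.24) and XCL1 (0.90 ± 0.28) were higher in T cell libraries, XCL1 without passing at a pseudocount of 0.1 (0.89). SPP1 (-1.31 ± 0.48) and CXCL10 (-1.17 ± 0.37) were lower, and neither passed with the number of genes detected as a covariate. MRC1 (-0.99 ± 0.34, limma adjusted p = 0.0107, lower in 30 of 51 donors) did not pass with the donor block (-0.33) or with genes detected as a covariate (-0.55). CXCL9 (-0.99 ± 0.42, limma adjusted p = 0.0399, lower in 35 of 51 donors) did not pass under 4 of the alternatives. XCR1 (-0.23 ± 0.17) did not pass. CLEC9A (-0.41 ± 0.18) did not pass either, and it passed with a pseudocount of 0.1 (-1.31), after rescaling without mitochondrial genes (-0.55) and without mixed libraries (-0.49).

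Of the lists, 6 of 6 pan T cell, 6 of 6 leukocyte, 7 of 7 naive and memory (IL7R 2.51 ± 0.32), 5 of 5 tissue residence, 7 of 8 cytotoxicity, 7 of 9 exhaustion, 6 of 7 T cell chemokine axis and 3 of 5 regulatory T cell genes were higher in T cell than in live libraries. The NK cell gene NCAM1 was lower (-0.87 ± 0.26), against 3 of 7 NK cell list genes higher. All 6 epithelial (KRT19 -3.21 ± 0.37, EPCAM -3.09 ± 0.36), 6 of 6 fibroblast (COL1A2 -2.28 ± 0.40), 5 of 5 neutrophil (CSF3R -2.84 ± 0.35), 4 of 5 mast cell and 3 of 4 B cell genes (BANK1 -2.55 ± 0.23) were lower. Of 18 CD206 macrophage genes 14 fell and MAF rose (1.95 ± 0.22), and with genes detected as a covariate 6 fell. Adjusted over the list alone, 16 fell. Limma called 7472 of 15954 genes, 3666 higher and 3806 lower (49.1% higher, 36.8% after rescaling without mitochondrial genes, 32.9% without the filter and 75.4% with genes detected as a covariate). The count was 9089 with donor as a block, 7161 within type A and 2790 within type B.

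Myeloid libraries, set against all viable cells, were higher in the growth factor receptor gene CSF1R by 2.79 ± 0.35 (6.91-fold, limma adjusted p = 5.18e-12, in 49 of 53 donors), in CLEC5A (2.61 ± 0.34), FCN1 (2.61 ± 0.37), the lysosomal gene CD68 (2.57 ± 0.32) and MS4A6A (2.54 ± 0.30). MRC1 was higher by 1.91 ± 0.33 (limma adjusted p = 3.71e-07), in 47 of 53 donors, with CXCL9 (1.61 ± 0.41), CXCL10 (1.51 ± 0.36), SPP1 (1.91 ± 0.47) and CLEC9A (0.86 ± 0.18). They were lower in CD3D (-3.48 ± 0.32), the granulysin gene GNLY (-3.48 ± 0.36), GZMK (-3.32 ± 0.32), IGHA1 (-3.30 ± 0.59), CD96 (-3.20 ± 0.34), CD8A (-2.90 ± 0.31) and XCL1 (-1.67 ± 0.27). CXCR3 (-0.81 ± 0.27, lower in 30 of 53 donors) and FLT3LG (-0.61 ± 0.23, lower in 34 of 53 donors) did not pass with donor as a block (-0.38 and -0.43), with quantile normalisation or with genes detected as a covariate. XCR1 differed by 0.10 ± 0.16 and did not pass.

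Of the lists, 10 of 10 pan myeloid, 15 of 18 CD206 macrophage (C1QC 2.28 ± 0.40, STAB1 2.37 ± 0.33), 7 of 7 class II, 4 of 4 cDC2 (CD1E 2.30 ± 0.34), 3 of 3 CXCR3 ligand, 3 of 5 mature dendritic cell, 3 of 6 cDC1 and 4 of 8 classical monocyte genes were higher in myeloid than in live libraries. SELENOP (0.14 ± 0.33), MAF (-0.19 ± 0.21) and SLC40A1 (-0.22 ± 0.26) were the CD206 macrophage genes that did not pass. The stress-responsive list split, with 4 of 15 higher (HMOX1 2.20 ± 0.30) and 5 lower (SLC2A1 -1.19 ± 0.24). The neutrophil list split as well, with CSF3R higher (0.96 ± 0.34) and 3 of 5 lower (CXCR1 -0.84 ± 0.26). All 8 cytotoxicity, 7 NK cell, 6 pan T cell, 6 epithelial, 6 fibroblast and 5 mast cell genes fell. None of 13 interferon response genes passed by limma, adjusted over all genes or over the list alone. With donor as a block 9 of the 13 rose, and with genes detected as a covariate 7 rose. Limma called 7771 of 15954 genes, 2131 higher and 5640 lower (27.4% higher, 47.2% with quantile normalisation, 65.8% with genes detected as a covariate). The median of all genes was -0.23, and -0.039 with quantile normalisation. The count was 8516 with donor as a block, 6299 within type A and 2483 within type B.

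Between tumour codes the myeloid libraries asked how the macrophage compartment varies with tumour type, each code being set against the equally weighted mean of the others. In CRC (n = 13 donors) the intestinal and colorectal genes CEACAM5 (4.98 ± 0.66, 31.6-fold, limma adjusted p = 5.35e-08, higher in 13 of 13) and GPX2 (4.33 ± 0.61) and the immunoglobulin gene IGHA1 (4.23 ± 0.95) were highest above the other codes. The complement gene C3 (-3.11 ± 0.61), the fractalkine receptor gene CX3CR1 (-2.73 ± 0.61) and LMO2 (-2.50 ± 0.45) were lowest, each below the median of the other codes in 13 of 13 donors. With scores of other cell types as covariates IGHA1 dropped to 2.09, CX3CR1 stood at -2.02, LMO2 at -1.94 and C3, little moved, at -2.98, and none of the 4 passed. Markers of other cells moved with this group: 5 of 6 epithelial (CLDN4 3.10 ± 0.59, EPCAM 2.84 ± 0.61), 2 of 2 intestinal (LGALS4 3.68 ± 0.47), 2 of 4 B cell (CD79A 2.14 ± 0.47, MS4A1 2.06 ± 0.53) and 1 of 3 plasma cell genes (JCHAIN 3.21 ± 0.80) rose. Of 18 CD206 macrophage genes 3 fell (F13A1 -2.39 ± 0.55, GPR34 -1.80 ± 0.46, MS4A7 -1.69 ± 0.50), 8 when adjusted over the list alone and none with the scores of other cells as covariates. No class II gene passed among all genes by limma, and 6 of 7 fell when adjusted over the list alone. CSF1R fell (-2.13 ± 0.49) and MRC1 did not pass (-0.49 ± 0.57).

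In KID myeloid libraries (n = 27) CX3CR1 (2.69 ± 0.46, limma adjusted p = 5.28e-05, in 24 of 27 donors), C3 (2.62 ± 0.47) and the actin-severing gene SCIN (2.52 ± 0.37) were higher than in the other codes. The matrix metalloproteinase genes MMP19 (10.6-fold lower, in 27 of 27) and MMP12 (-3.21 ± 0.48, lower in 26 of 27) and CEACAM5 (-2.91 ± 0.51) were lower. MRC1 was lower (-1.40 ± 0.44, limma adjusted p = 0.0338, in 19 of 27 donors), a call that ended without the filter on low values, while 3 other CD206 macrophage genes were higher: APOE (2.24 ± 0.50), SELENOP (1.65 ± 0.48) and GPR34 (1.34 ± 0.35). Adjusted over the list alone, 5 of the 18 rose and MRC1 fell. Of 5 mature dendritic cell genes 3 fell (CCL22 -2.45 ± 0.54, CCR7 -1.95 ± 0.47, LAMP3 -1.62 ± 0.39). The haem oxygenase gene HMOX1 (1.41 ± 0.32) and NDUFA4L2 (1.45 ± 0.38), a gene of the kidney epithelium list, rose, and the activin gene INHBA (-2.43 ± 0.50) fell. Of the heat shock genes HSPA1A (1.30 ± 0.42) and HSPA1B (1.40 ± 0.43) rose and the immediate early gene FOSB (-1.48 ± 0.36) fell. Epithelial markers moved with this group, 3 of 6 lower and 6 when adjusted over the list alone.

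In LUNG myeloid libraries (n = 10) MRC1 stood 2.41 ± 0.63 above the other codes (5.33-fold, limma adjusted p = 0.0463, in 9 of 10 donors), a call that ended under 5 alternatives, among them quantile normalisation and genes detected as a covariate. CCL4, a chemokine gene, was lower in 10 of 10 donors (-3.10 ± 0.67, limma adjusted p = 0.0116), and NAPSA, a lung aspartic protease gene, was higher (1.44 ± 0.38). None of 5 alveolar macrophage genes passed by limma among all genes, and 3 rose when adjusted over the list alone (MARCO 2.20 ± 0.65, MCEMP1 2.55 ± 0.79). Likewise none of 4 cDC2 genes and none of 8 cytotoxicity genes passed, and over the list alone 3 rose (CD1E 2.41 ± 0.74) and 4 fell (GZMB -2.78 ± 0.92). The small RNA genes MIR4257 (4.50 ± 1.09) and SNORD56B (3.50 ± 0.84) and the antisense gene CHMP1B-AS1 (3.27 ± 0.86) were higher. MIR4257 overlaps ADAMTSL4 and SNORD56B lies in SIPA1L1, so their reads are uncertain in origin. With library type as a covariate they stood at 4.08, 2.47 and 2.10 and did not pass, and none passed with a pseudocount of 0.1, with quantile normalisation or with scores of other cells as covariates.

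In HNSC myeloid libraries (n = 16) the inflammatory cytokine gene IL6 was 3.63 ± 0.69 higher (12.4-fold, limma adjusted p = 0.00558, in 15 of 16 donors), with the chemokine gene CXCL3 (2.60 ± 0.58) and ACOD1 (2.20 ± 0.45), the itaconate-producing enzyme of activated macrophages. CXCL3 and ACOD1 did not pass with scores of other cells as covariates (2.37 and 1.90) or without libraries of low quality (2.43 and 1.95), nor did CXCL3 with a pseudocount of 0.1 (2.93). KRT6A of the squamous list rose (2.18 ± 0.48), and 3 of 3 rose when adjusted over the list alone, as did 3 of 5 mature dendritic cell genes (CCR7 2.05 ± 0.57) and CCL3 (2.12 ± 0.57) and CCL4 (2.02 ± 0.55), none of which passed among all genes. In GYN (n = 37) the secretoglobin gene SCGB2A1 (3.22 ± 0.45, in 31 of 37 donors, limma adjusted p = 1.31e-06) and RHEX (1.68 ± 0.41) were higher. MUC16 (1.41 ± 0.30) and PAX8 (1.21 ± 0.36) of the 3 Mullerian genes rose, and neither passed with library type as a covariate. MIR12136 (-4.60 ± 1.08) and CHMP1B-AS1 (-2.82 ± 0.54) were lower. SNORD56B had a negative contrast (-2.21 ± 0.53) with a median of 0 TPM in GYN as in CRC, HNSC and KID, and 5 of 37 GYN donors lay above and none below the median of the other codes. With library type as a covariate these stood at -0.01, -1.61 and -1.15 and RHEX at 1.44, and none passed.

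A moderated F test over the 5 codes called 1679 of 15218 myeloid genes, and 544 within type B. Within type A, where only GYN, HNSC and KID had enough donors to be compared, it called 40. Single codes gave 423 for CRC (195 higher, 46.1%; 76.7% without the filter), 1072 for KID (701 higher, 65.4%; 51.4% with quantile normalisation), 404 for GYN (41 higher, 10.1%; 52.7% with quantile normalisation), 81 for LUNG (80 higher) and 15 for HNSC (all higher). The CRC count dropped to 22 with scores of other cells as covariates, and the GYN count to 26 with library type as a covariate. Within type B the counts were 69 for CRC (11 donors), 1 for GYN (14), 1 for HNSC (9), 769 for KID (19) and 56 for LUNG (10). Within type A they were 71 for HNSC (7 donors) and 9 for KID (9 donors). There limma called none for GYN (23 donors, 1002 genes at an unadjusted p under 0.05). CRC had 2 donors in type A and LUNG none, so the mean of the other codes left them out. By mean list score 11 of 36 lists differed between codes (permutation F test, adjusted over the 36), and mature dendritic cell was among them (F = 6.70, adjusted p = 0.00066), with a mean score of 0.60 ± 0.99 (SD) in HNSC and -0.41 ± 0.47 in KID. The CD206 macrophage (F = 2.81, adjusted p = 0.0815), stress-responsive (adjusted p = 0.475) and CXCR3 ligand scores (adjusted p = 0.694) did not pass.

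T cell libraries were compared between the codes as well. In KID (n = 19) the kidney transport regulator gene FXYD2 (3.54 ± 0.41, 11.7-fold, limma adjusted p = 4.14e-09, in 18 of 19 donors), the crystallin chaperone gene CRYAB (3.37 ± 0.57), C3 (2.75 ± 0.67) and the kidney transporter gene SLC17A3 (1.77 ± 0.35) were higher. IGHA1 (-3.80 ± 0.97), IGHA2 (-2.86 ± 0.67) and MIR3918 (-2.78 ± 0.69) were lower, IGHA1 without passing when mixed libraries were left out (-3.13). MIR3918 lies in SYTL3, so its reads are uncertain in origin. The homing receptor gene CCR7 (-2.03 ± 0.45) and LAYN (-1.46 ± 0.42), of the naive and memory list and of the exhaustion list, fell, as did FOSB (-1.55 ± 0.39). In CRC (n = 14) IGHA2 (3.53 ± 0.75), CEACAM5 (3.44 ± 0.50, in 14 of 14 donors) and the phospholipase gene PLA2G2A (1.93 ± 0.45) were higher, and CX3CR1 (-2.19 ± 0.46, lower in 14 of 14), MRPL13 (-1.77 ± 0.35) and CPQ (-1.66 ± 0.39) were lower. PLA2G2A did not pass with a pseudocount of 0.1 (2.99) or without the filter, CX3CR1 without mixed libraries (-2.03), and CPQ under 4 alternatives, among them quantile normalisation (-1.36). No epithelial or intestinal gene passed by limma among all genes, and 5 of 6 and 3 of 3 rose when adjusted over the list alone.

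In HNSC T cell libraries (n = 12) S100A2 (3.87 ± 0.67, limma adjusted p = 0.00161, in 11 of 12 donors), the basal keratin gene KRT5 (2.84 ± 0.52, in 12 of 12) and the matrix gene TNC (2.31 ± 0.44) were higher, with LAMP3 of the mature dendritic cell list (2.09 ± 0.48). TNC did not pass with a pseudocount of 0.1 (3.22) or without libraries of low quality (2.00). Over the list alone 4 of 4 mature dendritic cell, 3 of 3 squamous and 5 of 6 fibroblast genes (COL3A1 2.80 ± 0.68) rose. In GYN (n = 36) SCGB2A1 (2.71 ± 0.42), PPP1R2C (2.70 ± 0.38) and the epithelial gene WFDC2 (2.51 ± 0.56) were higher and TBC1D1 was lower (-0.73 ± 0.17, limma adjusted p = 0.0452, in 31 of 36 donors), a call that ended under 8 alternatives. WFDC2 did not pass without the filter, without libraries of low quality (2.26) or with library type as a covariate (2.60). MRC1, CXCL9, CXCL10, SPP1, CD8A, CXCR3, XCL1, FLT3LG and XCR1 passed in no code's T cell or myeloid libraries apart from MRC1 in KID and LUNG myeloid libraries. With scores of other cells as covariates MRC1 passed in KID (-1.15) and SPP1 in CRC T cell libraries (-2.39), and without libraries of low quality FLT3LG passed in KID myeloid libraries (0.80). The F test called 332 of 15319 genes, 45 within type A and 25 within type B. The counts were 508 for KID (383 higher, 75.4%; 45.2% with quantile normalisation), 22 for HNSC (all higher), 18 for CRC (9 higher, 50%; 84.2% with quantile normalisation) and 17 for GYN (5 higher, 29.4%; 5 of 5 with quantile normalisation). With library type as a covariate GYN kept SCGB2A1 and PPP1R2C alone. Within type A the counts were 35 for KID (10 donors), 15 for CRC (4) and 4 for GYN (22). KID had more within type B (9 donors) than within type A. Limma called none for HNSC in type A (3 donors, 705 at an unadjusted p under 0.05) and 1 in type B (9 donors). It called none in type B for CRC (10 donors, 834 unadjusted) or GYN (14 donors, 895 unadjusted).

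For CRC, GYN and HNSC, the only codes compared in live libraries, these libraries carried the clearest signs of tissue of origin. In CRC (n = 9) the regenerating protein gene REG1A (6.33 ± 0.70, 80.6-fold), the galectin gene LGALS4 (6.32 ± 0.62, limma adjusted p = 5.64e-10) and GPX2 (5.70 ± 0.74) were higher in 9 of 9 donors each, and 5 of 5 intestinal genes rose (FABP1 4.57 ± 0.60, VIL1 3.91 ± 0.49). In GYN (n = 29) SCGB2A1 (5.39 ± 0.82, in 27 of 29 donors), PAX8 (3.57 ± 0.58) and the ceruloplasmin gene CP (3.41 ± 0.68) were higher, and 5 of 5 Mullerian genes rose (MUC16 2.72 ± 0.60, EMX2 2.61 ± 0.39). In HNSC (n = 9) the keratin genes KRT6A (5.43 ± 0.72) and KRT14 (4.89 ± 0.76) and S100A7 (4.77 ± 0.46, limma adjusted p = 4.12e-10) were higher in 9 of 9 donors each, and 4 of 5 squamous genes rose (TP63 3.20 ± 0.57).

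Stromal and immune lists were set, in each code, against the mean of the other codes, and HNSC was not tested against GYN alone. In HNSC live libraries 5 of 5 endothelial (VWF 2.57 ± 0.54, PLVAP 2.38 ± 0.47), 4 of 6 fibroblast (LUM 3.03 ± 0.93), 4 of 5 mast cell (TPSAB1 3.81 ± 0.99), 4 of 5 mature dendritic cell (CCL22 3.41 ± 0.66, LAMP3 2.08 ± 0.42) and 4 of 5 regulatory T cell genes (FOXP3 2.20 ± 0.51) rose, while 4 of 6 epithelial genes fell (EPCAM -4.08 ± 0.77). Adjusted over the list alone 9 of 10 pan myeloid genes rose, against 2 among all genes. With scores of leukocytes and epithelium as covariates 2 endothelial and 1 mature dendritic cell gene stayed past the threshold. In GYN live libraries 5 of 5 mature dendritic cell (CCL22 -2.74 ± 0.51), 3 of 5 regulatory T cell (FOXP3 -2.02 ± 0.40, CCR8 -1.67 ± 0.41), 3 of 6 pan T cell (CD3E -1.66 ± 0.47), 3 of 5 B cell (CD79A -1.86 ± 0.55) and 4 of 9 exhaustion genes (CTLA4 -1.99 ± 0.55) fell. In GYN 1 of 5 endothelial and 2 of 5 mast cell genes fell and no fibroblast gene passed by limma, while in HNSC 2 of 9 exhaustion genes rose and no pan T cell or B cell gene passed. SPP1 was higher in GYN (1.82 ± 0.63, limma adjusted p = 0.0354, in 23 of 29 donors), a call that ended with library type or scores of other cells as covariates or without the filter. In CRC 3 of 18 CD206 macrophage genes fell (F13A1 -2.36 ± 0.67, STAB1 -2.03 ± 0.56, LYVE1 -1.88 ± 0.60), 13 when adjusted over the list alone, and 3 of 6 fibroblast genes fell (COL1A2 -3.55 ± 0.91). MRC1 did not pass in CRC (-1.01 ± 0.66), GYN (-0.37 ± 0.51) or HNSC (1.38 ± 0.66). XCR1 in HNSC and CXCR3 in GYN did not pass in the main fit. XCR1 passed with library type as a covariate (0.75) and without libraries of low quality (0.78). CXCR3 passed without libraries of low quality (-1.15).

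Limma called 1092 genes in CRC (611 higher, 56%; 73.1% without the filter), 3222 in GYN (774 higher, 24%; 53.1% with quantile normalisation) and 1519 in HNSC (1338 higher, 88.1%; 48.1% with quantile normalisation), and the F test called 4092 of 17376. The median of all genes in HNSC was 0.174, and -0.046 with quantile normalisation. With scores of leukocytes and epithelium as covariates the counts dropped to 282, 1338 and 265. Within types A and B they were 8 and 657 for CRC (3 and 6 donors), 707 and 1782 for GYN (23 and 6), and 325 and 53 for HNSC (4 and 5). Groups this small limit what these counts can show about library type. The median mitochondrial share was 35.93% in GYN, 27.04% in CRC and 19.90% in HNSC. By list score 13 of 36 lists differed between the codes (permutation F test), including mature dendritic cell (F = 16.2, adjusted p = 0.00024) with a mean of 1.08 ± 0.82 (SD) in HNSC and -0.30 ± 0.57 in GYN. The CD206 macrophage score did not pass (F = 4.20, adjusted p = 0.0502).

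**Figure D2:**
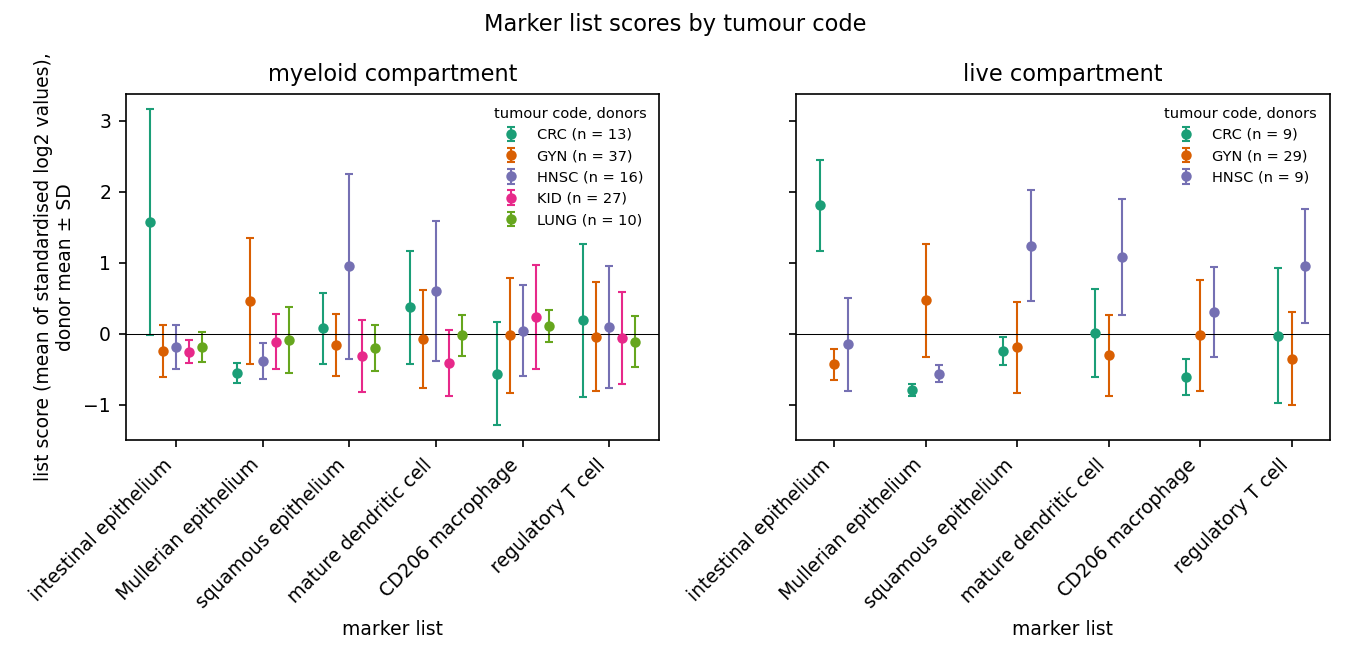
Mean score (mean of standardised log2(TPM + 1) over the list, no unit) of 6 gene lists by tumour code in myeloid and in live libraries, with error bars of 1 SD over donors. The mature dendritic cell score was 1.08 in HNSC and -0.30 in GYN live libraries, and 0.60 in HNSC and -0.41 in KID myeloid libraries.

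The slope of every myeloid gene on MRC1, within tumour codes, addressed what accompanies CD206 expression in tumour myeloid cells. RGL1, with the smallest p, rose by 0.44 ± 0.05 (SE, all myeloid donors) log2 per log2 unit of MRC1 (limma adjusted p = 1.24e-10), with MS4A4A (0.66 ± 0.08, limma adjusted p = 6.83e-10), the formyl peptide receptor gene FPR3 (0.54 ± 0.07), PMP22 (0.47 ± 0.06), F13A1 (0.57 ± 0.08), the complement receptor gene VSIG4 (0.59 ± 0.08), the scavenger receptor genes CD163L1 (0.55 ± 0.08) and CD163 (0.56 ± 0.08), PDGFC (0.46 ± 0.06) and the lectin gene CD209 (0.56 ± 0.08). Among the genes that fell, those named by the rule of smallest p included PPDPF (-0.26 ± 0.06), KLK10 (-0.33 ± 0.08) and SNHG9 (-0.28 ± 0.07). The others so named were KRT8 (-0.37 ± 0.10), KRT18 (-0.33 ± 0.10), CLDN3 (-0.34 ± 0.10), WFDC2 (-0.49 ± 0.13), ELAPOR1 (-0.31 ± 0.09), MUC13 (-0.22 ± 0.07) and ANO9 (-0.21 ± 0.06). These last 7 did not pass with scores of other cells as covariates. PPDPF (-0.19), KRT18 (-0.32), MUC13 (-0.24) and ANO9 (-0.20) did not pass without libraries of low quality, nor did MUC13 with a pseudocount of 0.1 (-0.26).

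CXCL9 rose with MRC1 by 0.44 ± 0.12 (limma adjusted p = 0.0093) and CXCL10 by 0.33 ± 0.11 (limma adjusted p = 0.0321). Both calls ended with quantile normalisation (0.33 and 0.26), with genes detected as a covariate (0.37 and 0.28) and without libraries of low quality (0.42 and 0.36). The CXCL10 call also ended without the filter (0.33), with scores of other cells as covariates (0.28) and rescaled without mitochondrial genes (0.30). CXCL11 (0.27 ± 0.10), SPP1 (0.21 ± 0.14), CLEC9A (0.12 ± 0.08) and XCR1 (0.00 ± 0.06) did not pass. Of the other CD206 macrophage genes 15 of 17 rose (LYVE1 0.63 ± 0.10, FOLR2 0.61 ± 0.09), with APOE (0.12 ± 0.11) and MAF (0.18 ± 0.07) not passing. All 7 class II (HLA-DRB1 0.44 ± 0.08) and 4 of 4 cDC2 genes (CD1E 0.55 ± 0.10) rose, as did 6 of 10 pan myeloid genes, 9 when adjusted over the list alone. Of 15 stress-responsive genes 3 rose (HK2 0.25 ± 0.07, VEGFA 0.23 ± 0.07, HMOX1 0.22 ± 0.07) and of 8 classical monocyte genes 4 rose, none of these with quantile normalisation or without libraries of low quality. Of 6 cDC1 genes BATF3 rose (0.20 ± 0.07), and of 13 interferon response genes 3 rose (IDO1 0.41 ± 0.11). Among T cell chemokine axis genes CCL3 rose (0.41 ± 0.10) and XCL2 fell (-0.27 ± 0.10).

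In all, 2309 of 15217 genes passed, 2255 rising and 54 falling (97.7% rising, 83.6% with quantile normalisation). The count was 216 within type A and 1256 within type B, and it dropped to 517 with quantile normalisation, 464 without libraries of low quality and 966 with genes detected as a covariate. MRC1 was itself higher in myeloid libraries with more genes detected (r = 0.274, permutation p = 0.00476, rho = 0.213, permutation p = 0.0308). Against the mitochondrial share of TPM MRC1 had r = -0.202 (permutation p = 0.0406) and rho = -0.147 (permutation p = 0.138). The stress-responsive score was higher with more genes detected (r = 0.305, permutation p = 0.00165, rho = 0.199, permutation p = 0.0452) and lower with a larger mitochondrial share (r = -0.38, permutation p = 7e-05, rho = -0.268, permutation p = 0.00618).

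**Figure D3:**
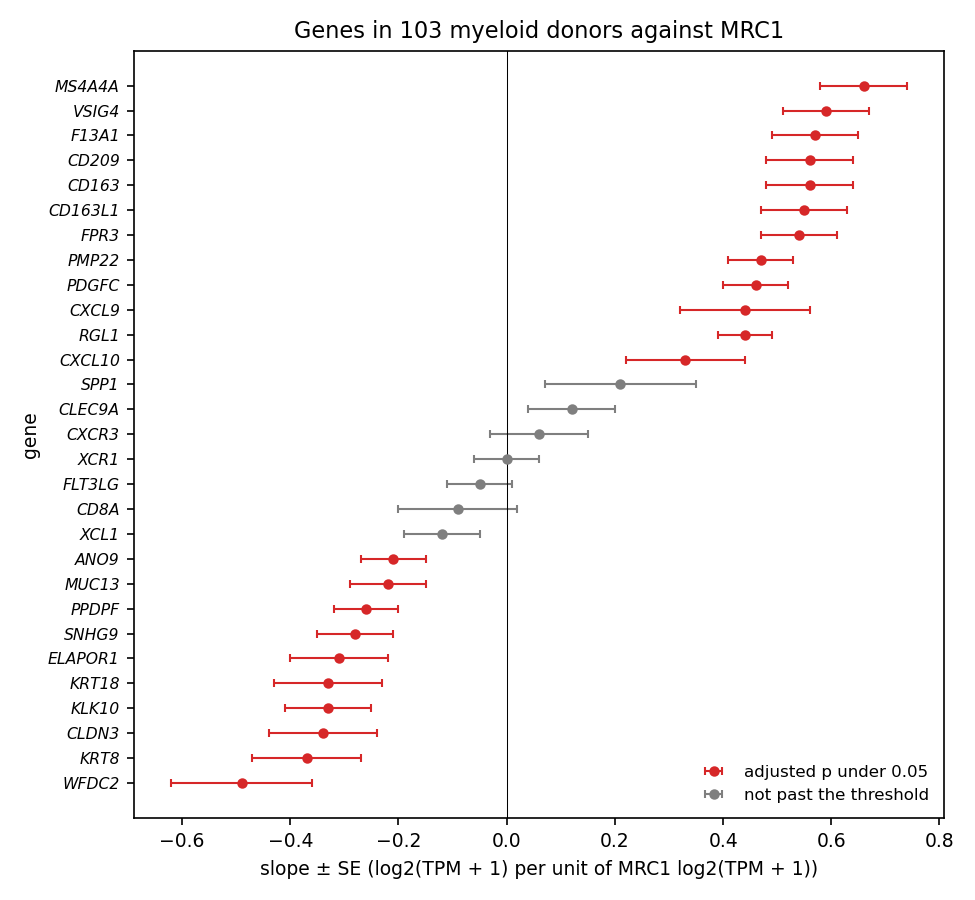
Slope of each gene's log2(TPM + 1) on that of MRC1 in myeloid libraries, within tumour codes (all myeloid donors), with error bars of 1 SE; red marks genes past the adjusted p threshold and grey those that are not. MS4A4A stood at 0.66, CXCL9 at 0.44 and SPP1 at 0.21.

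Whether T cells or the whole tumour vary with CD206 macrophages was asked with the score of the 18-gene CD206 macrophage list in the myeloid library of the same donor. Among T cell genes (n = 77 donors) GZMH, a granzyme gene, had a slope of 0.92 ± 0.20 log2 per SD of the score, CCL5 of 0.46 ± 0.17, CD8B of 0.41 ± 0.18 and CD8A of 0.24 ± 0.17. Limma called 0 of 15292 genes, with 1158 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0896. Adjusted over the list alone, 4 of 8 cytotoxicity, 1 of 2 CD8 T cell and 1 of 7 T cell chemokine axis genes rose. Among genes of live libraries (n = 53 donors) limma called 0 of 17086, with 1400 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0626. Within types A and B limma also called none, with 912 and 1352 T cell genes and 2738 and 656 live genes at an unadjusted p under 0.05.

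Within myeloid libraries the CD206 macrophage score rose with the CXCR3 ligand score (r = 0.394, 95% CI 0.217 to 0.546, permutation p = 4e-05, adjusted p = 0.00034 over 17 relations, all myeloid donors) and with the cDC1 score (r = 0.408, 95% CI 0.233 to 0.558, permutation p = 4e-05, adjusted p = 0.00034). Spearman's rho was 0.297 (permutation p = 0.00237) and 0.384 (permutation p = 0.0001). Without the 2 donors farthest from the median r was 0.345 and 0.384. Within type A r was 0.450 and 0.296, and within type B 0.368 and 0.496. The cDC1 relation did not pass within type A (permutation p = 0.0639), and with MRC1 alone in place of the list it was 0.068. Random lists matched on mean expression gave a median r of 0.288 and 0.25, and the relations stood at percentiles 74.7 and 87.3 of them. MRC1 and CXCL9 rose together (r = 0.357, permutation p = 0.00021, adjusted p = 0.000892, rho = 0.325, permutation p = 0.00074), with r = 0.335 without the 2 farthest donors, 0.530 in type A and 0.279 in type B. The stress-responsive score rose with the CXCR3 ligand score as well (r = 0.299, permutation p = 0.00204, adjusted p = 0.00694, rho = 0.254, permutation p = 0.00986), at 0.233 without the 2 farthest donors and percentile 80.5 of random lists (median 0.196). That relation did not hold within type A (r = 0.022, permutation p = 0.892) and held within type B (r = 0.421, permutation p = 0.0008). The stress-responsive score had no relation past the threshold with the cDC1 score (r = -0.046, adjusted p = 0.687), at percentile 1.2 of random lists (median 0.176).

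Between the fractions of a donor, the stress-responsive score of the myeloid library rose with the exhaustion score of the T cell library (r = 0.425, 95% CI 0.222 to 0.592, permutation p = 0.00014, adjusted p = 0.000793, rho = 0.389, permutation p = 0.00061, n = 77), with r = 0.428 without the 2 farthest donors. Random lists matched on mean expression gave a median r of 0.31 and a 95th percentile of 0.426, so the relation stood just below that bound, at percentile 94.8. Within type B r was 0.535 (n = 34) and within type A it was 0.009 (n = 31), so the relation did not hold within type A. The stress-responsive score also rose with T cell cytotoxicity (r = 0.303, permutation p = 0.00767, adjusted p = 0.0163, rho = 0.222, permutation p = 0.0513) and T cell CD8 scores (r = 0.278, permutation p = 0.0147, adjusted p = 0.025, rho = 0.200, permutation p = 0.08). Within types A and B r was -0.060 and 0.249 for cytotoxicity, and neither passed. For CD8 r was -0.285 in type A, and in type B 0.321 (permutation p = 0.0633, rho = 0.352, permutation p = 0.0422). There the p of rho, not adjusted, was under 0.05 and that of r was not. Without the 2 farthest donors r was 0.332 and 0.271. Random lists gave medians of 0.29 and 0.21 (percentiles 58.4 and 74.1), so both lay within what random genes give. With live CD8, NK cell and cDC1 scores (n = 53) r was -0.151, -0.198 and -0.142, and none passed (adjusted p = 0.354, 0.219 and 0.354). These stood at percentiles 12.8, 1.3 and 2.2 of random lists, whose median r was 0.031, 0.09 and 0.125.

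The CD206 macrophage score of the myeloid library rose with T cell cytotoxicity (r = 0.302, 95% CI 0.084 to 0.493, permutation p = 0.00742, adjusted p = 0.0163, n = 77), while rho was 0.164 (permutation p = 0.154) and r without the 2 farthest donors was 0.236 (permutation p = 0.0407, adjusted p = 0.0693), so the call ended without them. With the T cell CD8 score r was 0.252 (permutation p = 0.0266, adjusted p = 0.0412, rho = 0.136, permutation p = 0.237). It dropped to 0.168 without the 2 farthest donors (permutation p = 0.15), so that relation rests on them. With the live NK cell score r was 0.335 (permutation p = 0.0145, adjusted p = 0.025, rho = 0.318, permutation p = 0.0213, n = 53), and with the live cDC1 score r was 0.375 (permutation p = 0.00598, adjusted p = 0.0163, rho = 0.390, permutation p = 0.00407). Without the 2 farthest donors these were 0.304 (adjusted p = 0.0583, so that call ended) and 0.365 (adjusted p = 0.0241). Within tumour codes the live relations were 0.201 and 0.193 and did not pass (permutation p = 0.175 and 0.169). T cell exhaustion (r = 0.028, adjusted p = 0.81) and live CD8 scores (r = 0.148, adjusted p = 0.354) did not pass. Within types A and B r was 0.067 and 0.327 for T cell cytotoxicity, -0.058 and 0.294 for T cell CD8, 0.128 and 0.480 for live NK cell and 0.437 and 0.239 for live cDC1 scores. Of these only the live cDC1 relation in type A had an unadjusted p under 0.05 (permutation p = 0.0199). Within codes it was 0.337 there (permutation p = 0.108). Among random lists the T cell cytotoxicity relation stood at percentile 99.8, T cell CD8 at 95.2, live NK cell at 96.2 and live cDC1 at 97.8.

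The difference between the CD206 macrophage and stress-responsive scores was tested against each of 8 scores, to ask whether the 2 lists differ in their relations. Here values were centred per tumour code and permuted within codes. These r are thus within codes, while the relations above, unless marked, are over all donors. The cDC1 score of myeloid libraries rose with the difference (r = 0.282, permutation p = 0.00276, adjusted p = 0.0221), and did not pass with a pseudocount of 0.1 (0.238) or without libraries of low quality (0.247). T cell exhaustion (r = -0.272, permutation p = 0.0213, adjusted p = 0.0851) and live NK cell scores (r = 0.312, permutation p = 0.0343, adjusted p = 0.0915) did not pass. CXCR3 ligand (r = 0.048, adjusted p = 0.745), T cell CD8 (r = -0.061, adjusted p = 0.745), T cell cytotoxicity (r = -0.034, adjusted p = 0.786), live CD8 (r = 0.204, adjusted p = 0.288) and live cDC1 scores (r = 0.232, adjusted p = 0.196) did not pass. None of the 17 relations differed between tumour codes past the threshold (smallest interaction permutation p = 0.0554).

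**Figure D4:**
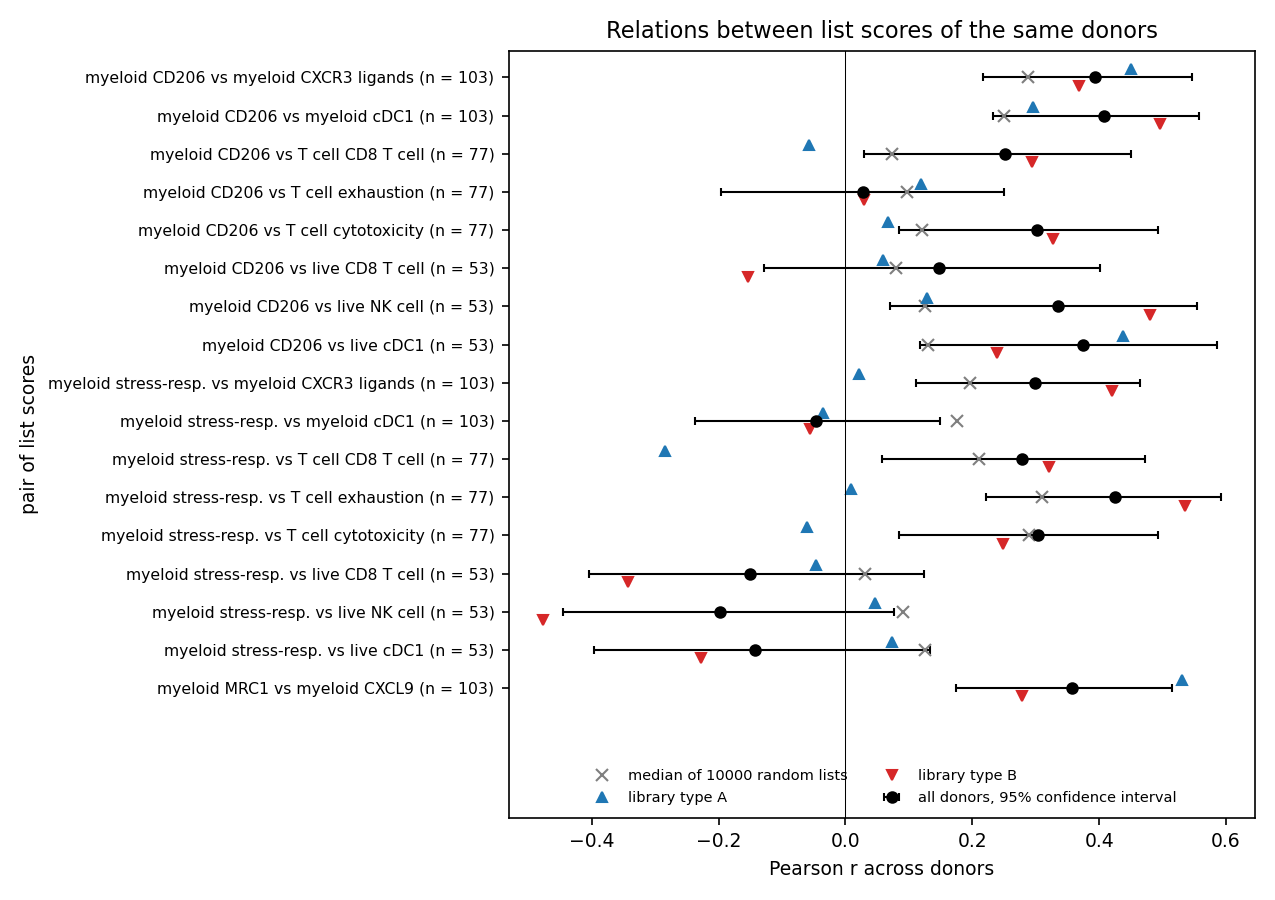
Pearson's r of 17 relations between scores (points, with 95% confidence intervals), the median r of random lists matched on mean expression (crosses) and r within library types A and B (triangles). The CD206 macrophage and cDC1 scores of myeloid libraries stood at 0.408, and the stress-responsive and T cell exhaustion scores at 0.425.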

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

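The tests of MRC1 against library quality, the number of libraries and other cells, and of the CXCR3 ligand relation against library type, library quality and other cells, were chosen after seeing the results, while the splits of the samples and the test against random lists were written before. A Dixon test for a sample far from the others was made in 38 sets of values, of which 5 passed. Chance alone passes about 1 in 20 where values are normally distributed. Values near 0, as those of XCR1 and CD8A below, need not be, so 5 of 38 cannot be read as an excess. In LUNG myeloid libraries (n = 10, critical value 0.466) the highest CD8A lay at 4.05 log2(TPM + 1) against 0.04 to 0.66 in the others (gap over range 0.846), and the highest XCL1, in the same library, at 2.92 against 0.00 to 1.53 (0.475). The lowest MRC1 there lay at 2.90 against 6.91 to 9.37 (0.621) and the highest XCR1 at 1.49 against 0.00 to 0.01 (0.99), in other libraries. In HNSC live libraries (n = 9, critical value 0.493) the lowest SPP1 lay at 0.00 against 4.32 to 7.99 (0.54).

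Chance alone was excluded for most of the gene counts by 100 splits of the samples, where only 1, the real one, called as many genes. For the fractions the real counts and the highest of the other splits were 9858 and 0 for T cell against myeloid, 7472 and 9 for T cell against live, and 7771 and 5 for myeloid against live. In myeloid libraries they were 423 and 22 for CRC, 404 and 0 for GYN, 81 and 4 for LUNG, and 1679 and 99 for the F test. For KID, with 1072 genes, no other split came near that count. In T cell libraries they were 22 and 5 for HNSC, 508 and 4 for KID, and 332 and 1 for the F test. In live libraries they were 1092 and 176 for CRC, 3222 and 11 for GYN, 1519 and 253 for HNSC, and 4092 and 281 for the F test. For the MRC1 slope they were 2309 and 2. For HNSC myeloid libraries 4 of 100 splits called at least the real 15, the highest many more, for CRC T cell libraries 2 called at least 18, the highest 82, and for GYN T cell libraries 2 called at least 17, the highest 21. Splits that call many more than the real one may point to a structure of the samples other than the codes, or to single libraries far from the others, and neither was tested. For the slopes on the CD206 macrophage score, with 0 genes called by limma, all 100 splits called as many in T cell (highest 42) and all 100 in live libraries (highest 1) by construction, so the splits say nothing there.

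Without libraries of low quality 19.2% of the calls on MRC1 stayed past the threshold. The smaller number of libraries did not account for the loss, since 0 of 100 random removals of 11 other myeloid libraries, as many per code, kept as few, and the lowest share that stayed was 57.8% (median 84.5%). The slopes of the genes called fell to a median 0.734 of their value without libraries of low quality, against 1.024 in the random removals. Those libraries may thus have raised the number of genes called. Whether they did so by their quality or by their level of MRC1 was not tested. Library quality so measured did not account for the whole excess of rising over falling genes. At least 84.8% of calls rose in the fits without those libraries or with genes detected as a covariate. That lowest share was below the share in the main fit, so library quality may add to the excess. Given the pan T cell, epithelial, fibroblast and B cell scores 99.3% of calls rose. Falling genes such as KRT8 and CLDN3 lost their calls given those scores, which by itself raises that share. The share thus cannot tell whether cells of other types added to the excess. A measurement of MRC1 protein on single cells of the same tumours would test the relation without library quality.

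The relation of CD206 macrophage and CXCR3 ligand scores could reflect a library-wide shift, because r = 0.394 stood at the 74.7th percentile of random lists matched on mean expression, whose median r was 0.288. Library type did not account for it (the smaller r within types was 0.368). Given the tumour code and the pan T cell, epithelial, fibroblast and B cell scores the partial r was 0.372, so cells of those types did not account for it. Scores of dendritic cells, monocytes and endothelial cells were not included, so such cells were not tested. Both scores fell with the mitochondrial share (r = -0.298 and -0.357, permutation p = 0.00218 and 0.00032) and rose with genes detected (r = 0.337 and 0.228). Library quality so measured did not account for the whole relation, with a partial r of 0.311 (permutation p = 0.00144) given both and the code, but may add to it. A macrophage state that makes CXCL9 beside CD206 thus remains a hypothesis. Staining of CXCL9 and CD206 in the same cells would test it.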

How the results depend on the processing

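No named gene or relation past the threshold turned its direction under an alternative fitted to all library types. Within type A, where the types were split, 3 relations that had passed were negative without passing (-0.285, -0.06 and -0.058). There 301 of 345 GYN (87.2%) and 992 of 1034 KID myeloid calls (95.9%) kept their direction, as did 2210 of 2290 MRC1 calls (96.5%). The GYN and KID myeloid contrasts of type A left out CRC and LUNG. In T cell libraries of type A 13 of 14 GYN (92.9%) and 20 of 21 HNSC calls (95.2%) kept it. The split of calls into higher and lower moved with the scaling, as given beside the results, and the stress-responsive and live CD8 relation, which did not pass, ran from -0.295 to 0.26. Of the gene counts, 177 of the values under alternatives stayed within the same range, 22 were larger and 32 smaller by over 1.5 times. Robust eBayes and the first specimen only moved no count by that much (LUNG myeloid had 72 and 90), though robust eBayes ended the calls of MRC1 and CHMP1B-AS1 in LUNG myeloid libraries. Of the values of named genes 2995 kept their side of the threshold, 97 lost the call and 9 gained one. The donor block gave 10223, 9089 and 8516 genes for the fractions, and apart from the values beside the results it changed no other call of a count. The counts of T cell against myeloid ranged from 9383 to 11396 over 11 alternatives, and those of myeloid against live from 6299 to 11553. Depth is unknown, so what it limits could not be given. The cause was not tested for the changes below, except where the alternative removes samples or adds genes by its own construction.

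With a pseudocount of 0.1 the counts in myeloid libraries were 271 for CRC, 3 for HNSC, 10 for LUNG and 1118 by the F test, in T cell libraries 3 for HNSC, 263 for KID and 168 by the F test, 3753 for the MRC1 slope and 16 for the live slope on the CD206 score, and the cDC1 difference was r = 0.238. Without the filter they were 11687 for T cell against live, 1008, 56 and 328 for CRC, HNSC and LUNG myeloid, and 40, 11 and 146 for CRC, GYN and HNSC T cell libraries. With quantile normalisation they were 18 for LUNG myeloid, 5 and 13 for GYN and HNSC T cell, 1642 for CRC live and 517 for the MRC1 slope. With genes detected as a covariate they were 45 for LUNG myeloid, 10 for HNSC T cell, 966 for the MRC1 slope and 1 for the T cell slope on the CD206 score.

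With scores of other cells as covariates the counts were 22, 230 and 1080 for CRC, GYN and the F test in myeloid, 36, 44, 14, 1054 and 783 for CRC, GYN, HNSC, KID and the F test in T cell, 282, 1338, 265 and 1476 for CRC, GYN, HNSC and the F test in live libraries, and 7 for the live slope. Rescaled without mitochondrial genes they were 6 and 6 for GYN and HNSC T cell, 1336 for the MRC1 slope and 3 for the live slope. Without libraries of low quality they were 743, 2167 and 2622 for CRC, KID and the F test in myeloid, 3 and 5 for GYN and HNSC T cell, 464 for the MRC1 slope and 4 for the live slope, and 22 lists differed between codes in live libraries. With library type as a covariate GYN had 26 in myeloid and 2 in T cell libraries. Without mixed libraries GYN and HNSC T cell had 68 and 11, and the T cell slope 2.

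Among relations 154 values kept their side of the threshold and 32 did not. The CD206 macrophage and T cell CD8 relation did not pass at 0.248 (quantile normalisation), 0.215 (without mitochondrial genes), 0.156 (without low quality), 0.23 (without mixed libraries), 0.216 (partial given other cells), 0.106 (MRC1 alone) and 0.223 (library type). With T cell cytotoxicity it did not pass at 0.261 (without mitochondrial genes), 0.234 (without low quality) and 0.208 (MRC1 alone). With live NK cells it did not pass at 0.27 (quantile normalisation), 0.279 (without mitochondrial genes), 0.247 (partial given genes detected), 0.173 (partial given other cells), 0.27 (MRC1 alone) and 0.164 (library type). With live cDC1 it did not pass at 0.322 (quantile normalisation), 0.104 (partial given genes detected), 0.16 (partial given other cells) and 0.259 (library type), and with myeloid cDC1 at 0.068 (MRC1 alone).

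The stress-responsive and CXCR3 ligand relation did not pass at 0.217 (quantile normalisation) and 0.231 (without mitochondrial genes). With T cell CD8 it did not pass at 0.207 and 0.204 in those settings, 0.257 (without low quality), 0.237 (partial given genes detected) and 0.18 (SPP1 alone). With T cell cytotoxicity it did not pass at 0.245 and 0.23 in those settings and 0.147 (SPP1 alone), and with T cell exhaustion at 0.184 (SPP1 alone). The cDC1 difference did not pass at 0.247 without low quality, and the T cell exhaustion difference passed at -0.396 (without mixed libraries), -0.374 (partial given other cells) and -0.299 (unstandardised mean).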

Other observations

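The tests on the interferon response below were written before their values were computed, except that against library quality, which was chosen after seeing the data, as was the set of same-list relations. Interferon response genes, which cells induce on sensing type I or II interferon, varied together in separately sorted T cell and myeloid cells of the same donors (r = 0.795, permutation p = 1e-05, adjusted p = 4.15e-05 over 108 relations, rho = 0.763, permutation p = 1e-05, n = 77). That p is the smallest the permutations can give. Without the 2 farthest donors r was 0.742, and within types A and B it was 0.729 and 0.83. The immediate early and heat shock score was shared as well (r = 0.789, permutation p = 1e-05, rho = 0.704, permutation p = 1e-05), with 0.706 without the 2 farthest donors and 0.771 and 0.857 within the types. Random lists of 13 genes, matched to the interferon list and scored in both fractions, gave a median r of 0.548 and a 95th percentile of 0.663. The mature dendritic cell (r = 0.614, permutation p = 1e-05) and CXCR3 ligand scores (r = 0.481, permutation p = 3e-05) passed but lay below that 95th percentile, and lists of their own size were not drawn.

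Lineage scores varied in this. Intestinal (r = 0.788, adjusted p = 4.15e-05), epithelial (r = 0.716), plasma cell (r = 0.678), plasmacytoid dendritic cell (r = 0.52), neutrophil (r = 0.359) and mast cell scores (r = 0.289, adjusted p = 0.0166) passed. Without the 2 farthest donors r was, in that order, 0.598, 0.678, 0.578, 0.391, 0.415 and 0.297. For the intestinal score rho was 0.325 and r within codes was 0.63. Random lists of the size of these lists were not drawn, and the mast cell relation did not hold within type B (r = -0.02, permutation p = 0.911, against 0.476 in type A). The pan T cell (r = -0.02, permutation p = 0.863), cytotoxicity (r = 0.03, permutation p = 0.8), CD8 (r = 0.029, permutation p = 0.803) and CD206 macrophage scores (r = 0.16, permutation p = 0.164) did not pass between T cell and myeloid libraries. Of the 36 lists, 20 passed between T cell and myeloid, 31 between T cell and live and 31 between myeloid and live libraries. Between T cell and live libraries the Mullerian score led (r = 0.863, permutation p = 1e-05, n = 51), and mast cell (r = 0.711, permutation p = 1e-05) and regulatory T cell scores (r = 0.483, permutation p = 0.00028) passed.

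An interferon response common to the cells of a tumour would be consistent with the relation within tumour codes (r = 0.796). The relation stood at the 100th percentile of random lists scored in both fractions, whose median r was 0.548. It thus exceeded what random genes share, and a library-wide shift may account for part of it. Those lists join unrelated genes, so the percentile cannot exclude such a shift. Given the pan T cell and pan myeloid scores of both libraries the partial r was 0.749. Cells of the other sorted fraction thus did not account for the relation. Nor did library type, with 0.729 as the smaller value within types. Library quality did not either, with a partial r of 0.775 given genes detected and the mitochondrial share of both libraries. Handling of the specimen before sorting may still add to it, because the immediate early and heat shock score was shared as well, and interferon measured in the tissue would separate the 2.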
